A study of Mus musculus with 6 samples.

How the data were processed

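mRNA-seq libraries from 3 untreated and 3 LPS-treated (4 h) samples of RAW 264.7 cells were analysed, grouped by the treatment labels and numbered as in the sample titles. Per the labels' protocols, total RNA was extracted and libraries were made with a TruSeq RNA kit. Per the submitters' processing notes, TopHat2 2.1.0, HTSeq and edgeR were used, with the builds mm10 and GRCm38; the role and settings of each, including the strand setting of the counting and the gene annotation, are not given in the sources used here. The authors deposited 1 table of CPM values, read counts scaled to a common library total, for all 6 libraries, with 24421 gene rows and the HTSeq rows for reads assigned to no gene. No other column of per-sample values was present. Without a stated strand setting, reads of a gene and an overlapping antisense gene cannot be told apart, and genes with near-identical copies are uncertain.

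Each CPM value in the deposited table was a whole multiple of the smallest value above 0 of its library (100% of values within 0.01 of a whole number), so the reads were recovered. The libraries held 6233092 to 7988673 reads. The deposited CPM are scaled to the total of all rows: the rows that name no gene held 30.4% to 37.8% of reads, with 22.9% to 25.7% not uniquely aligned and 1.21% to 1.32% ambiguous. Reads outside annotated features were 10.0% ± 0.692 of the untreated and 6.41% ± 1.56 of the LPS libraries (SD, n = 3, two-sided exact permutation p = 0.1, the smallest that 3 against 3 allows). These rows were left out of the tests and of the library sizes used with edgeR and DESeq2, and stayed in the denominators of the deposited CPM. In the table, 27 gene rows had a date as a name, as spreadsheet programs make from some symbols, and were kept under it. At these depths 3 counts correspond to 0.137 CPM over the untreated and 0.144 CPM over the LPS group, and intervals and floors cover counting error only. Read counts of libraries of the same group differed by 4.8 to 42.6 times the sampling variance (chi-square per degree of freedom), so no library was a copy of another.

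Genes with at least 1 CPM in at least 3 libraries (10110 genes) were tested on log2(CPM + 1) with limma-trend (limma 3.58.1, R 4.3.3), two-sided, with group as the only term and Benjamini-Hochberg adjusted p under 0.05 as a call. Gene lists of 20 pathways and 7 marker sets were fixed from textbook knowledge before the data were examined, as were the test, the rule for named genes and most alternatives. The 21 lists with at least 5 tested members were tested with camera at a preset inter-gene correlation of 0.01, and again with an estimated correlation. Only the chemokine list passed with the latter, and none with a replicate block added. The estimates ran from −0.00713 (unfolded protein and integrated stress response) to 0.914 (osteoclast markers), and all but the former were above the preset 0.01. Where the estimates hold, the preset p-values of those lists are too small. With 6 libraries the estimate leaves camera few degrees of freedom and little power. A list that did not pass it is therefore not shown to be unchanged. The other lists had too few tested members, and no mitochondrially encoded transcript of the 13 in that marker list was a row of the table. Named genes were the 8 largest increases and the 8 largest decreases among called genes that separated the groups and reached a mean of 10 CPM in the higher group. The rule added up to 2 called members per pathway list in its main direction and 1 in the other, the most abundant member of each marker list, and Parp14, Ifnb1, Tnf and Actb. Genes named to spell out counts of 5 or fewer, uncalled list members, Bcl2a1a and its copies, Bcl2l1, Dtx3l, Il1rn, Kif20b, Kif23, Hsp90b1, Calr, Pdia4, Hemk1 and Olfr1033 were chosen after their values were seen. Results for some genes are not reported here. Irg1 is the older symbol of Acod1. Coordinates are from GENCODE M21 on GRCm38, matched by symbol.

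Both groups carry the replicate numbers 1 to 3 in the sample titles. Deviations from the group means of same-numbered libraries correlated across genes at 0.263, 0.237 and 0.414, and those of different numbers at −0.315 to 0.127, 2 of 6 being over 0.1. As every same-numbered pair was over 0.1, the numbers were treated as pairing the libraries. Both different-numbered pairs over 0.1 joined replicates 1 and 2 (0.121 and 0.127). A difference shared by the replicate 3 libraries raises these pairs and the same-numbered ones alike. The bound alone therefore does not show pairing of numbers 1 and 2, whose same-numbered values were higher. The planned test has no block, and the fit with a replicate block is given where it changes a call or moves a count over 1.5 times. It is also given for Fos, Trib3, Edem1 and Nfatc1, whose calls were lost in fits that left out 1 library. Those fits had no block either, so each left 1 library without its pair. Correlations of log2 values across genes were 0.958 to 0.986 within and 0.847 to 0.872 between groups.

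The alternatives were pseudocounts of 0.25 and 5, no filter and a filter at 5 CPM, median-of-ratios and quantile scaling, a replicate block, leaving out each library, a robust variance fit, a test against a fold of 1.5, fry for the lists, and edgeR 4.0.16 (quasi-likelihood) and DESeq2 1.42.0 on the recovered reads. On these reads edgeR called 3910 genes and DESeq2 3864. Added after the data were seen were CPM of gene rows only, leaving out both replicate 3 libraries, edgeR with a replicate block, and camera with an estimated correlation and a replicate block.

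The tests were checked on simulated counts for the 10110 genes, 200 of them changed. Means were those of the untreated libraries and totals those of the 6 libraries. In the data 43.4% of tested genes were called, which makes the adjusted threshold less strict. The rates below therefore hold for the simulated setting alone. limma-trend recovered 0% of genes changed 1.5-fold, 30% at 2-fold, 92% at 4-fold and 100% at 8-fold, and 2.63% of its calls were false. edgeR recovered 4%, 36%, 92% and 100%, and DESeq2 8%, 46%, 92% and 100%. Figures were drawn with matplotlib 3.10.9.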

Results

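mRNA was sequenced from RAW 264.7 cells, a mouse macrophage line, of wild-type genotype for Parp14. The 6 libraries formed 2 groups of 3: untreated cells, and cells exposed for 4 h to lipopolysaccharide (LPS), the outer membrane glycolipid of Gram-negative bacteria that is sensed through Toll-like receptor 4. Values were deposited as CPM, read counts scaled to a common library total, from which whole read counts were recovered. The untreated libraries held 6424775, 7556708 and 7988673 reads and the LPS libraries 7622898, 6233092 and 6998022. Of these, 4260269 to 5132600 reads per library were assigned to genes. Between 12352 and 13552 genes had at least 1 read in a library. The labels number the replicates but name no separate cultures, so p-values measure only the spread between these libraries, whose source, technical or biological, is not given. Part of the spread followed the replicate number. In both libraries of numbers 1, 2 and 3, 9, 6 and 91 genes deviated 2-fold together, against at most 2 for pairs of different numbers. The question set by the series design was which transcripts of wild-type macrophages change under LPS, in a series on PARP14, an ADP-ribosyltransferase, and interferon-inducible proteins.

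LPS raised 15 of 15 tested cytokine, 14 of 14 chemokine and 35 of 37 antiviral effector transcripts and lowered 29 of 30 cell cycle transcripts. The cytokine and chemokine lists held 19 and 17 genes before the filter. A gene under 1 CPM in all untreated libraries entered only if all LPS libraries reached 1 CPM. Such a gene could only be seen to rise. As lists all 4 passed at a preset inter-gene correlation, and with an estimated correlation only the chemokines did. The latter test has little power with 6 libraries, so it does not set the chemokines apart from the other lists. Il1b, encoding interleukin 1 beta, went from 0.685 ± 0.718 to 2279 ± 982 CPM (SD, n = 3), a log2 fold change of 10.37 (SE 0.39). Irg1, the enzyme that makes itaconate, went from 8.83 ± 4.43 to 3976 ± 228 CPM. Parp14, named in the series title, rose 16.9-fold, from 11.6 ± 3.36 to 196 ± 42.1 CPM. Ccnd1, encoding cyclin D1, fell from 372 ± 56.0 to 49.8 ± 21.1 CPM. Principal component 1 held 77.9% of the variance and separated the groups.

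By limma-trend on log2(CPM + 1), with Benjamini-Hochberg adjustment, 1325 of the 10110 tested genes were higher and 3063 lower in LPS, and 740 and 1385 of these changed at least 2-fold. Log2 fold changes here are on the log2(CPM + 1) scale, which understates the change of low genes. The 3 LPS values lay wholly above or below the 3 untreated ones for 5584 genes (55.2%, against 10% by chance). The median log2 fold change of all tested genes was −0.25 on the deposited scale and −0.01 after median-of-ratios rescaling. Higher genes made up 30.2% of the calls on the deposited scale, 51.5% (2072 higher, 1948 lower) after that rescaling, 42.3% after quantile normalization and 50.1% (1960 higher, 1950 lower) with edgeR on the recovered reads. The direction of a small change therefore depends on the scaling. Replicate 3 of both groups stood apart from the others on principal component 2 (12.3% of the variance) and carried higher osteoclast marker transcripts. Without both replicate 3 libraries, 1549 genes were higher and 3430 lower, and 4077 of the 4388 calls were also made.

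The 8 genes named for the largest increases encode secreted mediators, apart from Irg1, a theme that was not tested. Among genes that separated the groups and reached 10 CPM, they were Il1b, Il1a, Csf3, Cxcl2, Irg1, Ccl5, Saa3 and Il27, with log2 fold changes from 10.37 to 7.93. Csf3, encoding granulocyte colony-stimulating factor, went from 0.128 ± 0.125 to 889 ± 582 CPM, a ratio of 6730 with a 95% counting interval of 2300 to 32600. Ccl5, a chemokine, went from 1.86 ± 0.145 to 1003 ± 184 CPM (log2 fold change 8.44, SE 0.16, adjusted p = 3e-08). The largest decreases were in C130050O18Rik, Slc16a12, Cytip, Slc5a3, Ccne2, Id2, Bhlhe41 and Gpr183, with log2 fold changes from −4.69 to −3.45. Slc5a3, a myo-inositol transporter, fell from 177 ± 68.6 to 12.6 ± 2.82 CPM. Id2, an inhibitor of basic helix-loop-helix factors, fell from 114 ± 28.2 to 9.10 ± 2.74 CPM.

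All 15 tested members of the cytokine list, which includes the inhibitor Il1rn, and all 14 tested chemokines rose, each at least 2-fold, and the counts were 15 and 14 adjusted over the list alone. With no filter, 15 of the 19 listed cytokines and 14 of the 17 listed chemokines were called higher, and none lower. Their median log2 fold changes were 5.12 and 5.18. Tnf (chromosome 17, 35199381 to 35202007) rose 47.3-fold, from 59.6 ± 10.2 to 2818 ± 1276 CPM (log2 fold change 5.43, SE 0.34, adjusted p = 1.15e-05). Cxcl2, a neutrophil-attracting chemokine, went from 2.79 ± 1.19 to 3061 ± 1968 CPM. In these lists LPS replicate 3 was the lowest LPS library for Il1b (1159 CPM), Cxcl2 (790 CPM) and Tnf (1372 CPM). camera with a preset correlation gave adjusted p = 3.43e-16 for the cytokines and 2.23e-17 for the chemokines. With an estimated correlation the values were adjusted p = 0.0681 and 0.0346, and the chemokines were the only list below the threshold. With a replicate block added the chemokines did not pass either (adjusted p = 0.158, in a range of 3.21e-22 to 0.158 over 18 alternatives).

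**Figure D1:**
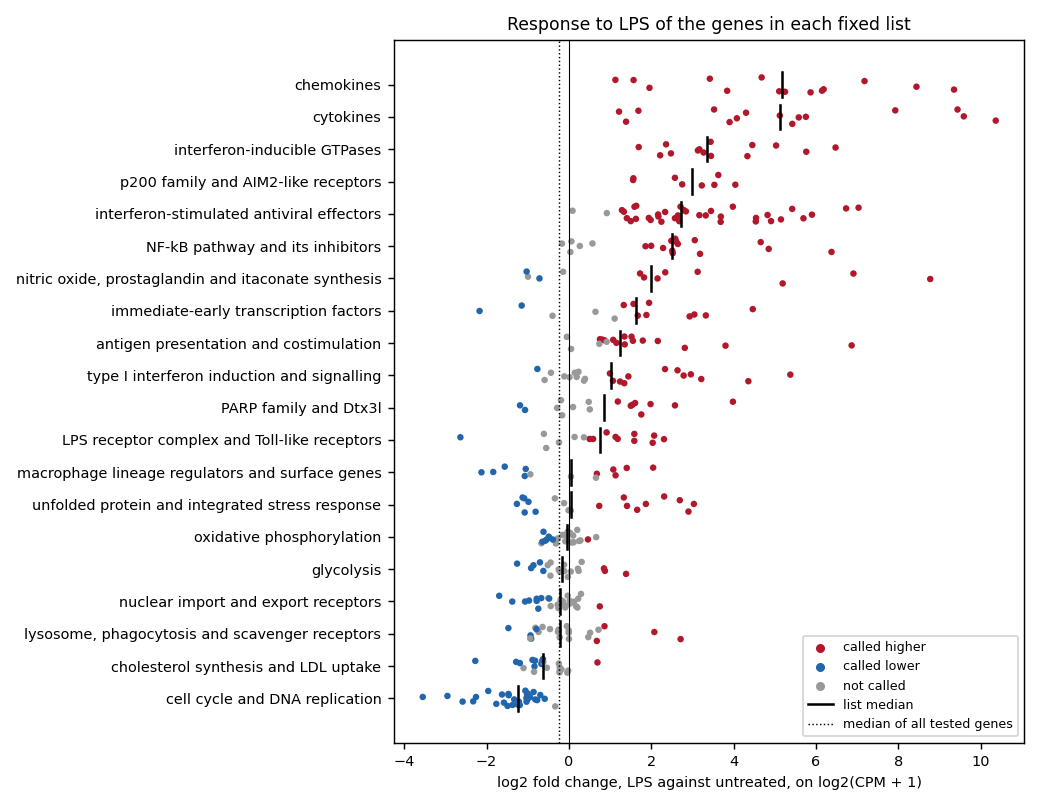
Log2 fold change of LPS against untreated on log2(CPM + 1) (horizontal axis) for each tested gene of the 20 fixed pathway lists (1 row per list). Points are genes, red where called higher, blue where called lower and grey where not called; black bars are list medians, from 5.18 for chemokines to −1.23 for cell cycle genes, and the dotted line is the median of all tested genes at −0.25.

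Interferon-response genes rose together. Of 37 interferon-stimulated antiviral effectors, 35 rose and none fell (36 higher adjusted over the list alone), with a median log2 fold change of 2.71. Samhd1 and Ifi27 were not called, but Samhd1 was higher with a replicate block (adjusted p = 0.000653, in a range of 0.000653 to 0.189 over 19 alternatives) and with median-of-ratios rescaling, edgeR and DESeq2. Rsad2, encoding the antiviral enzyme viperin, went from 1.98 ± 0.595 to 456 ± 332 CPM, and Ifit1, which binds foreign RNA, from 10.1 ± 4.69 to 1138 ± 402 CPM. LPS replicate 3 had the highest value of both, 835 CPM for Rsad2 and 1597 CPM for Ifit1. All 14 tested interferon-inducible GTPases, of 18 listed, rose (14 adjusted over the list alone), with a median of 3.36. Among them Gbp3 went from 1.22 ± 0.417 to 212 ± 113 CPM and Gbp2 from 0.630 ± 0.368 to 109 ± 94.9 CPM. All 8 tested members of the p200 family of DNA-sensing proteins rose (8 adjusted over the list alone), with a median of 2.99, led by Pyhin1 at 4.04 (SE 0.34) and Mnda at 3.63 (SE 0.29). Many members of these 3 lists have near-identical copies, so reads could be split or lost between them and their single values are uncertain. camera gave adjusted p = 2.87e-32, 3.03e-15 and 1.68e-09 for the effectors, GTPases and p200 family. With the estimated correlations, 0.526, 0.668 and 0.551, these were adjusted p = 0.0791, 0.0959 and 0.0922.

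Of 22 genes of type I interferon induction and signalling, 12 rose, 1 fell and 9 were not called, and the counts were the same adjusted over the list alone. Ifnb1, encoding interferon beta (chromosome 4, 88522025 to 88522774), went from 0.0417 ± 0.0723 to 7.25 ± 1.97 CPM. Its ratio of 160 rested on 1 untreated read and had a 95% counting interval of 28.3 to 6370. Socs3, a feedback inhibitor of cytokine signalling, rose by 5.38 (SE 0.19) and Ikbke, a kinase acting on interferon regulatory factors, by 4.36 (SE 0.16) on the log2 scale. Mavs, the mitochondrial adaptor of RNA sensors, fell by 0.768 (SE 0.195). The Mavs call was lost without untreated replicate 1, where the log2 fold change was −0.67, and with DESeq2 (−0.54). The median of the list was 1.03, with camera adjusted p = 2.95e-08 and adjusted p = 0.0722 with an estimated correlation. Without LPS replicate 2, or with a replicate block, 2 of its members were lower, against 1 with edgeR and that block.

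In the PARP family list, which includes the PARP9 partner Dtx3l and shares a gene with the antiviral effector list, 8 of 16 tested members rose and 2 fell (8 and 2 adjusted over the list alone). Parp14 (chromosome 16, 35832874 to 35871544) had a log2 fold change of 3.98 (SE 0.24, adjusted p = 8.78e-06) and values of 14.2, 7.81 and 12.9 CPM untreated and 158, 189 and 241 CPM under LPS. Parp10 rose from 23.9 ± 2.06 to 152 ± 49.8 CPM. Parp1, the main DNA damage-responsive member, fell from 154 ± 13.7 to 67.7 ± 13.1 CPM, and Tnks2 fell by 1.07 on the log2 scale (SE 0.17). The list median was 0.85, with camera adjusted p = 0.000505 and adjusted p = 0.238 with an estimated correlation. Of the 11 tested genes with the symbol stem Parp, a grouping chosen after the result was seen, 5 rose and 1 fell. As a group these did not pass (camera adjusted p = 0.0528, and 0.999 with an estimated correlation).

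**Figure D2:**
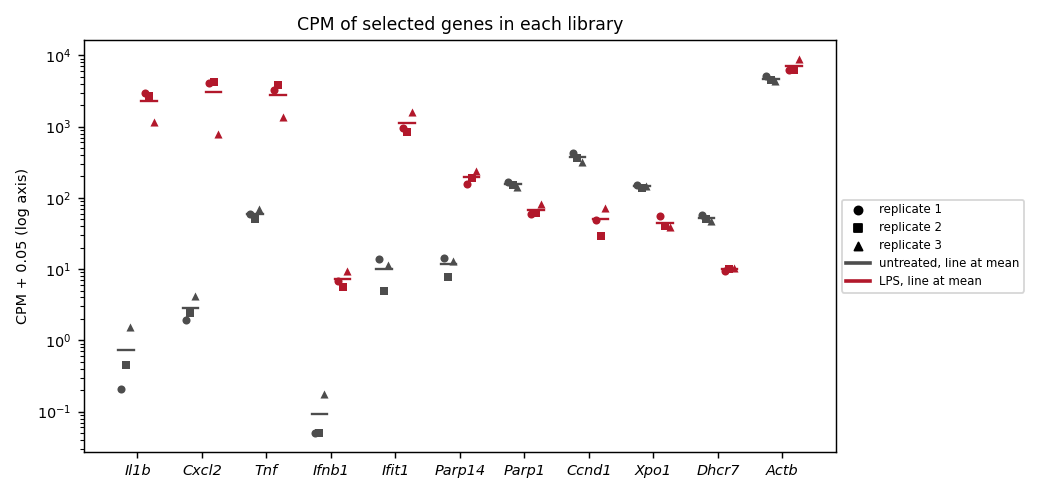
CPM plus an offset of 0.05 (vertical log axis) of 11 genes in each library, untreated in grey and LPS in red. Symbols mark the replicate number and horizontal lines the group mean of 3 libraries; the LPS mean is 2279 CPM for Il1b and 196 CPM for Parp14, and Actb, at 4722 and 7125 CPM, was not called.

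NF-kB pathway genes and their inhibitors rose in 14 of 19 cases and none fell (14 adjusted over the list alone), with a median log2 fold change of 2.51. Nfkbiz, an inducible nuclear cofactor of NF-kB, went from 3.71 ± 0.985 to 422 ± 191 CPM. Tnfaip3, the ubiquitin-editing inhibitor A20, went from 1.87 ± 0.766 to 81.4 ± 18.7 CPM. Rela, Ikbkb, Ikbkg, Bcl3 and Tnip3 were not called. Of 14 immediate-early transcription factors, 9 rose and 2 fell (9 and 2 adjusted over the list alone). Myc rose by 4.47 (SE 0.46) and Junb by 3.33 (SE 0.32), while Klf4 fell by 1.15 (SE 0.26) and Fos by 2.17 (SE 0.57). Fos lost its call without untreated replicate 3 (log2 fold change −1.80), LPS replicate 1 (−1.86) or LPS replicate 2 (−1.75), each leaving 1 lower gene, and with edgeR (−1.68) and DESeq2 (−1.66). Fos kept its call with a replicate block (adjusted p = 4.56e-06). camera gave adjusted p = 2.07e-14 for the NF-kB list and 2.78e-06 for the immediate-early list. With an estimated correlation these were adjusted p = 0.0681 and 0.0722.

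Receptor and effector genes of LPS sensing moved both ways. Among 16 genes of the LPS receptor complex and Toll-like receptors, 10 rose and 1 fell, with 10 and 2 adjusted over the list alone. Irak2, a signalling kinase, rose by 2.31 (SE 0.38) and Tlr1 by 2.07 (SE 0.26), while Tlr13, a sensor of bacterial ribosomal RNA, fell by 2.64 (SE 0.36) on the log2 scale. Tlr4 itself was not called, at −0.61 (SE 0.26), but was lower with a replicate block (adjusted p = 0.0118, in a range of 0.0118 to 0.540 over 19 alternatives) and without LPS replicate 1 (−0.89). edgeR with a replicate block did not call it (−0.37). The number of lower members was 3 with a replicate block (1 with edgeR and that block) and 2 without LPS replicate 1, LPS replicate 3 or both replicate 3 libraries. Among 12 genes of nitric oxide, prostaglandin and itaconate synthesis, 8 rose and 2 fell (8 and 2 adjusted over the list alone). Ptgs2, the inducible cyclooxygenase, went from 16.3 ± 1.43 to 2200 ± 838 CPM. Pla2g4a fell by 0.717 (SE 0.140) and Ptgs1, the constitutive cyclooxygenase, by 1.03 (SE 0.27). The Ptgs1 call was lost without untreated replicate 1 (−0.95) or untreated replicate 2 (−0.85), leaving 1 lower gene each time, and with quantile normalization (−0.70), and the Pla2g4a call with DESeq2 (−0.44). The list medians were 0.75 and 1.99, with camera adjusted p = 0.000137 and 1.54e-05. With an estimated correlation these were adjusted p = 0.0722 and 0.0681.

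Antigen presentation and costimulation genes rose in 14 of 18 cases and none fell (14 adjusted over the list alone), with a median of 1.25. Cd40, a costimulatory receptor, went from 2.65 ± 0.924 to 418 ± 55.5 CPM, and Cd274, encoding PD-L1, from 1.43 ± 0.332 to 36.9 ± 23.6 CPM. B2m, Erap1, Psmb9 and Tap2 were not called. Psmb9 and Tap2 were higher with a replicate block (adjusted p = 0.0208 and 0.0124, in ranges of 0.00486 to 0.238 and 0.00292 to 0.226 over 19 alternatives) and with median-of-ratios rescaling, edgeR and DESeq2. camera gave adjusted p = 2.16e-10, and adjusted p = 0.101 with an estimated correlation. The class I genes of this list are near-identical in sequence and uncertain singly.

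Cell cycle and DNA replication genes fell in 29 of 30 cases, 23 of them at least 2-fold, and none rose (29 lower adjusted over the list alone). The median was −1.23 as deposited and −0.97 after median-of-ratios rescaling, under which 27 fell. Ccne2, encoding cyclin E2, fell from 51.1 ± 4.71 to 3.52 ± 1.08 CPM. Ccnd1 had a log2 fold change of −2.95 (SE 0.28, adjusted p = 0.000102). camera gave adjusted p = 1.48e-11, and adjusted p = 0.0791 with an estimated correlation.

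Cholesterol synthesis and LDL uptake genes fell in 9 of 22 cases and rose in 1 (10 and 1 adjusted over the list alone). Dhcr7, which makes cholesterol from 7-dehydrocholesterol, fell from 52.0 ± 5.20 to 9.90 ± 0.518 CPM. Sqle, squalene epoxidase, fell from 144 ± 22.4 to 62.3 ± 30.7 CPM. Idi1 rose by 0.692 (SE 0.199), a call lost without untreated replicate 1 (0.65) or untreated replicate 2 (0.687). The list median was −0.64, and camera gave adjusted p = 0.0619, which did not pass. With a replicate block it was adjusted p = 0.0143 and 14 members were lower, against 8 with edgeR and that block. With an estimated correlation it did not pass (adjusted p = 0.715, and 0.620 with a replicate block added), and the range over the 18 alternatives was 0.00104 to 0.715. The list passed without untreated replicate 1 (adjusted p = 0.0456), untreated replicate 2 (0.0365), LPS replicate 3 (0.00104) or both replicate 3 libraries (0.00113). The lower members numbered 18 without LPS replicate 3, 14 without both replicate 3 libraries, and 6, 5 and 5 without untreated replicates 1, 2 and 3. They numbered 5 without LPS replicate 1, without LPS replicate 2, and after median-of-ratios rescaling.

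Nuclear import and export receptors, the carriers of proteins through nuclear pores, fell in 9 of 27 cases and rose in 1 (9 and 1 adjusted over the list alone). Xpo1, the main export receptor, fell from 146 ± 5.84 to 44.9 ± 8.80 CPM, and Kpna2, an importin alpha, from 626 ± 35.2 to 242 ± 37.95 CPM. Ipo13 rose from 42.8 ± 9.29 to 71.5 ± 4.69 CPM. The list median was −0.21 as deposited and 0.06 after median-of-ratios rescaling, under which 5 rose and 7 fell. camera did not separate the list from other genes (adjusted p = 0.288, and adjusted p = 0.702 with an estimated correlation). The list was lower by fry, which does not compare it with other genes (adjusted p = 0.00398, in a range of 0.00398 to 0.751 over 18 alternatives).

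Glycolysis genes went both ways, with 3 of 20 higher and 5 lower (3 and 5 adjusted over the list alone). Slc2a1, the glucose transporter GLUT1, rose from 165 ± 10.6 to 435 ± 45.2 CPM, and Hk2 and Pfkp rose by 0.850 (SE 0.135) and 0.873 (SE 0.156). Hk1 fell from 71.1 ± 15.0 to 30.4 ± 12.8 CPM, and Pfkm, Pgam1, Pkm and Tpi1 were the others called lower, at −0.92, −0.705, −0.62 and −0.86. Each lost its call in 4 or 5 of the 6 fits that left out 1 library, with log2 fold changes there of −0.80 to −0.87, −0.54 to −0.76, −0.56 to −0.62 and −0.705 to −0.92. They also lost it with DESeq2 (−0.78, −0.40, −0.37 and −0.55), and all but Pfkm with median-of-ratios rescaling (−0.44, −0.36 and −0.60) and edgeR (−0.42, −0.39 and −0.57). Between 1 and 2 members were lower when any 1 library other than LPS replicate 3 was left out, and 10 were lower without LPS replicate 3 or without both replicate 3 libraries. After median-of-ratios rescaling 5 rose and 2 fell, and the median moved from −0.17 to 0.07. camera gave adjusted p = 0.533, and adjusted p = 0.871 with an estimated correlation.

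Of 28 oxidative phosphorylation genes 1 rose and 7 fell, and 0 rose and 6 fell adjusted over the list alone. Sdhd, a subunit of succinate dehydrogenase, fell from 345 ± 9.80 to 221 ± 25.4 CPM. Ndufv1 rose by 0.461 (SE 0.160), a call kept only when LPS replicate 1 was the library left out, with log2 fold changes of 0.32 to 0.58 over all 6 such fits, and lost with no filter and with CPM of gene rows only (0.38). The number of lower members was 4 without untreated replicate 2 or LPS replicate 2 and 3 without untreated replicate 3, and with a replicate block 2 rose and 8 fell, or 5 and 2 with edgeR and that block. After median-of-ratios rescaling 6 rose and 1 fell, and the median moved from −0.05 to 0.22. camera gave adjusted p = 0.927, and adjusted p = 0.957 with an estimated correlation.

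Lysosome, phagocytosis and scavenger receptor genes rose in 4 of 23 cases and fell in 4 (4 and 4 adjusted over the list alone). Axl, a receptor for apoptotic cells, went from 0.600 ± 0.192 to 9.52 ± 1.67 CPM and Fcgr2b, the inhibitory Fc receptor, from 20.8 ± 6.54 to 96.4 ± 45.3 CPM. Fcgr1 and Ctsb were the other members called higher, and Fcgr3, Lamp1, Trem2 and Tyrobp the members called lower. The calls of Fcgr1 (0.86) and Ctsb (0.68) were each lost in 3 of the 6 fits that left out 1 library, with log2 fold changes there of 0.82 to 0.91 and 0.55 to 0.73, and that of Ctsb also with no filter and with quantile normalization (0.27). Fcgr3 fell from 5.88 ± 2.73 to 1.495 ± 0.976 CPM. With a replicate block 6 were higher and 9 lower, and without both replicate 3 libraries 6 and 8. Without untreated replicate 1 or untreated replicate 2 only 2 were higher, and without LPS replicate 3 9 were lower. The list median was −0.23 as deposited and 0.04 after median-of-ratios rescaling, under which 6 rose and 4 fell. Quantile normalization gave 3 higher and 7 lower, and CPM of gene rows only gave 4 and 7. The osteoclast marker Atp6v0d2 is also in this list, whose median was 0.40 (untreated) and 0.56 (LPS) higher on the log2 scale in replicate 3 than in replicates 1 and 2. camera gave adjusted p = 0.533, and adjusted p = 0.871 with an estimated correlation.

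Macrophage lineage regulators and surface genes split, with 5 of 13 higher and 5 lower (5 and 6 adjusted over the list alone). Mpeg1, a pore-forming protein, rose from 115 ± 22.2 to 478 ± 86.4 CPM and Spi1, the lineage factor PU.1, from 10.4 ± 2.21 to 29.4 ± 7.34 CPM, and Ccr2, Itgam and Cd14 were the others called higher. The Itgam call was lost without untreated replicate 2 (0.54), untreated replicate 3 (0.65) or LPS replicate 1 (0.48), and with CPM of gene rows only (0.60). Cx3cr1, the fractalkine receptor, fell from 140 ± 61.7 to 30.0 ± 9.19 CPM, and Csf1r, Cebpa and Lyz2 were among the others that fell. The Lyz2 call was lost with no filter and with quantile normalization (−0.78). camera gave adjusted p = 0.464, and adjusted p = 0.688 with an estimated correlation. The glycolysis, lysosome and oxidative phosphorylation lists had medians and means below 0 but a camera direction of up, because camera compares a list with other genes, whose median was below 0 too. The macrophage lineage list had a median of 0.05, a mean of −0.12 and a camera direction of up.

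In the unfolded protein and integrated stress response list 9 of 19 genes rose and 6 fell (9 and 6 adjusted over the list alone). Ppp1r15a, a phosphatase subunit that acts on eIF2 alpha, went from 20.2 ± 0.735 to 185 ± 110 CPM. Trib3, a pseudokinase, rose by 3.04 (SE 0.87), a call lost without LPS replicate 1 (2.81) or LPS replicate 2 (2.63) and with a robust variance fit. Trib3 kept its call with a replicate block (SE 0.235, adjusted p = 6.57e-07). Edem1, Hsp90b1, Calr and Pdia4, which serve protein folding and degradation in the endoplasmic reticulum, were among the 6 lower members. The last 3 were picked after their values were seen, and that role was not tested as a set. Edem1 fell by 1.27 (SE 0.34), a call lost without untreated replicate 3 (−0.997), LPS replicate 1 (−1.15) or LPS replicate 2 (−1.02). Edem1 kept its call with a replicate block (adjusted p = 5.04e-05). The lower members numbered 3 without untreated replicate 1 or untreated replicate 3, and 2 without LPS replicate 1 or LPS replicate 2. camera gave adjusted p = 0.0275, and adjusted p = 0.101 with an estimated correlation. The call was also lost after median-of-ratios rescaling (adjusted p = 0.107) and quantile normalization (0.168), within a range of 0.00459 to 0.359 over 18 alternatives.

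Markers of other cell types were low apart from those of osteoclasts, the bone-resorbing cells that share the macrophage lineage. No lymphocyte, neutrophil and mast cell, or fibroblast, epithelial and endothelial marker passed the filter, and their highest values were 0.751 CPM (Cd8a), 0.525 CPM (S100a8) and 0.525 CPM (Kdr). Of 2 tested dendritic cell markers Xcr1 rose, from 0.494 ± 0.262 to 5.28 ± 1.87 CPM, and Itgax was not called (1 higher adjusted over the list alone). Both were higher with a replicate block, without untreated replicate 3 (Itgax at 1.36) and without both replicate 3 libraries, but with edgeR and a replicate block Itgax was not called (1.395). Of 7 tested osteoclast markers, 1 rose, Mmp9 at 4.25 (SE 0.35), and 1 fell, Nfatc1 at −2.20 (SE 0.68), with the same counts adjusted over the list alone. Acp5 was at 1.87, 13.9 and 132 CPM in untreated replicates 1, 2 and 3 and at 1.71, 22.1 and 213 CPM under LPS. The median marker was 2.02 (untreated) and 2.87 (LPS) higher on the log2 scale in replicate 3 than in replicates 1 and 2. The Nfatc1 call was lost without untreated replicate 3 (−1.66), LPS replicate 1 (−1.61) or LPS replicate 2 (−2.01), leaving 0 lower markers, and with edgeR (−1.82), DESeq2 (−1.80) and a robust variance fit. Nfatc1 kept its call with a replicate block (adjusted p = 4.36e-06). With a replicate block 3 markers were higher and 2 lower, and without both replicate 3 libraries 3 were higher and 1 lower. camera gave adjusted p = 0.182 for the osteoclast list (adjusted p = 0.715 with an estimated correlation), and 0.0361 without untreated replicate 3, in a range of 0.0361 to 0.715.

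**Figure D3:**
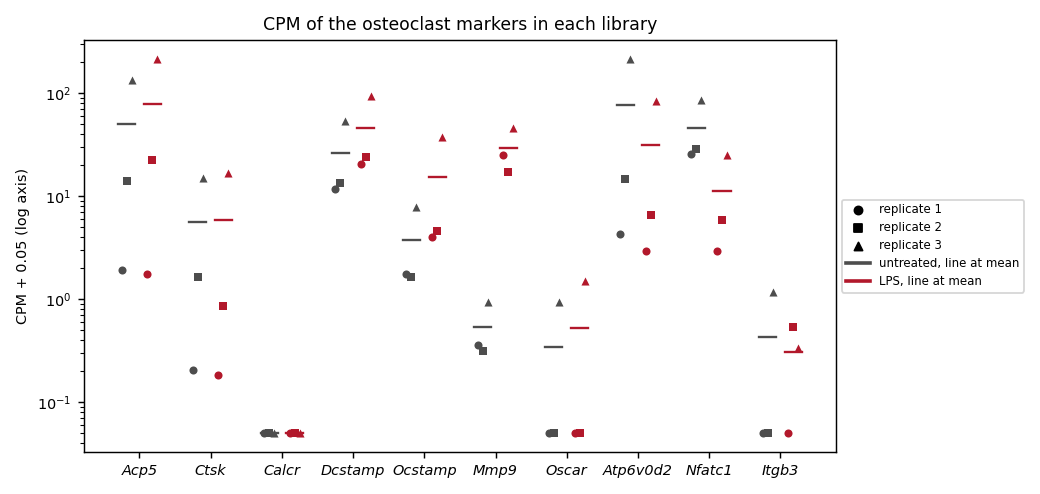
CPM plus an offset of 0.05 (vertical log axis) of the 10 osteoclast markers in each library, untreated in grey and LPS in red, with symbols for the replicate number and lines at the group mean of 3 libraries. Acp5 was at 132 CPM in untreated replicate 3 and 213 CPM in LPS replicate 3, against 1.71 to 22.1 CPM in the other libraries.

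Of 4 tested structural or non-polyadenylated RNAs, Hist1h1c fell by 0.847 (SE 0.202) and the others were not called (0 higher and 1 lower adjusted over the list alone). Its call was lost with quantile normalization (−0.51) and DESeq2 (−0.74). With a replicate block, without LPS replicate 3 and without both replicate 3 libraries, 2 were lower, against 1 with edgeR and a replicate block. Rn45s, the ribosomal RNA precursor, was at 53540 ± 10930 and 59000 ± 14110 CPM. Actb, encoding beta-actin, was at 4722 ± 434 CPM untreated and 7125 ± 1509 CPM under LPS (log2 fold change 0.58, SE 0.21, adjusted p = 0.0511). Its adjusted p was 0.0249 with a replicate block, and it ranged from 2.7e-05 to 0.258 over 19 alternatives. It also passed with edgeR, DESeq2, median-of-ratios rescaling and quantile normalization, and without LPS replicate 1 (log2 fold change 0.67).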

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

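The alternatives with gene rows only, without both replicate 3 libraries, edgeR with a replicate block and estimated correlation with a replicate block were chosen after seeing the data. Of 114 comparisons of counts with an alternative, 93 stayed within 1.5 times. Of 1949 for single named genes, 1825 kept direction and call, 86 lost and 34 gained the call, and 4 reversed; of 378 for lists, 339, 29, 9 and 1. Called genes numbered 956 to 1471 higher and 2223 to 3670 lower when 1 library was left out, at least 2-fold 697 to 766 and 1260 to 1617, and lists 13 to 14 higher and 1 to 2 lower. Median-of-ratios rescaling gave 2072 higher and 1948 lower genes and 876 lower at least 2-fold; DESeq2 gave 2053 and 1811 and edgeR 1950 lower, which change the test as well as the scaling. CPM of gene rows only gave 1148 higher and 3566 lower. A pseudocount of 5 left 634 genes lower at least 2-fold, since it shrinks low genes, and the test against a fold of 1.5 left 756, a stricter question. With a replicate block 1547 genes were higher and 3538 lower, sharing 4369 of the 4388 calls, and edgeR with a replicate block gave 2206 higher. Among named genes and lists the replicate block changed no call other than those of Actb, Samhd1, Tlr4, Psmb9, Tap2, Itgax and the cholesterol list, and moved no other count given here over 1.5 times than those printed beside their lists. Lists called lower were 2 instead of 1 with no filter, quantile normalization, the replicate block or without both replicate 3 libraries, the added list being cholesterol synthesis, and 3 with fry, which does not compare with other genes. The lists added by fry were nuclear import and export (adjusted p = 0.00398) and oxidative phosphorylation (adjusted p = 0.0463), the latter up by camera but far from the threshold. With an estimated correlation, a test of little power with 6 libraries, 1 list was called higher and 0 lower, and with a replicate block added 0 and 0 (lowest adjusted p = 0.158). Acp5 ranged from −1.174 (without LPS replicate 3) to 1.977, being also −0.909 without untreated replicate 1, and Rn45s from −0.010 (without LPS replicate 2) to 0.34 when 1 library was left out and was −0.071 without both replicate 3 libraries; neither was called in these fits, but Acp5 was called higher with edgeR and a replicate block (0.806). For the reversals, the cause was not tested. In simulated data, where far fewer genes changed than were called here, the test recovered 0% of 1.5-fold and 30% of 2-fold changes. The adjusted threshold was less strict in the real data, so these rates do not give the sensitivity of the test there. A missing call still does not show that a change is absent.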

Other observations

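The symbol families below, and the tests of other cell types, shared cultures, scattered receptor reads, a weaker stimulus and scaling, were chosen only after the result was seen. Among 122 families of genes sharing a symbol stem, tested with camera, genes of the Bcl stem rose in 8 of 16 cases and fell in 2, and genes of the kinesin (Kif) stem fell in 14 of 24 cases and rose in 1. Bcl2l1, encoding the survival protein BCL-XL, went from 39.7 ± 6.46 to 396 ± 58.7 CPM (SD, n = 3), a log2 fold change of 3.29. Bcl2a1a went from 0.0936 ± 0.0825 to 47.5 ± 28.4 CPM. Its near-identical copies Bcl2a1b, Bcl2a1c and Bcl2a1d were also called higher, and their single values are uncertain. These members of the stem are not independent, which its count and test do not allow for. Kif20b and Kif23, motors of cell division, fell from 74.1 ± 1.46 to 25.3 ± 9.81 CPM and from 76.3 ± 5.34 to 28.3 ± 5.15 CPM. The adjusted p was 0.000167 for the Bcl stem and 0.0387 for the kinesins, and adjusted p = 0.677 for both with an estimated correlation. After median-of-ratios rescaling the medians kept their sign, at 1.00 and −0.63.

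Hemk1 was at 0.132 and 0.160 CPM in the replicate 2 libraries, against 3.15 to 8.29 CPM elsewhere.

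Replicate 3 of both groups shared higher osteoclast markers, with medians 2.02 and 2.87 above replicates 1 and 2 on the log2 scale. GC content and gene length were argued against, since the lower median was still 1.99 after their trends were removed. Lymphocytes, neutrophils, mast cells, fibroblasts, epithelial and endothelial cells were argued against too, as 0 of their markers reached 1 CPM in both replicate 3 libraries. The highest of these markers in any library was 0.751 CPM, known before the test was chosen. Dendritic cells cannot be told apart, as 1 of their 9 markers reached 1 CPM in both, Itgax at 3.38 and 4.14 CPM. That rests on Itgax alone, which was also at 3.05 CPM in LPS replicate 2. Flt3, Zbtb46, Ccr7, Batf3, Clec9a, Cd209a and Siglech were at 0 to 0.125 CPM in both replicate 3 libraries. Separate cultures or sublines behind the numbers stay open and are a candidate explanation: 9, 6 and 91 genes deviated 2-fold in the same direction in both libraries of numbers 1, 2 and 3, the lowest count being 6, against at most 2 for pairs of different numbers. No biological explanation was tested, as the labels name no difference between replicates.

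Untreated replicate 2 alone held reads of 930 genes (1148 reads), against 183 to 304 such genes in the other libraries. Depth was argued against, since 894 such genes were left after thinning all libraries to 4260269 gene reads, against 293 in the next library, while RNA from another cell type cannot be told apart, since the 10 leading genes held 3.48% of those reads but 762 of the 930 genes had a single read, which leaves that share deciding nothing. Reads scattered over the genome, as from genomic DNA, cannot be told apart either: 74 of 1456 olfactory and vomeronasal receptor genes had a read there, against at most 30 elsewhere, but 54 of the 74 are among the 930 genes, so the count restates the pattern. The read rate of these receptors, 56.1 CPM of gene reads against 83.2 in LPS replicate 2, met the bound set beforehand against genomic DNA, but that bound was wrong because the single gene Olfr1033 held 73.5% of the receptor reads of that LPS library. In untreated replicates 1, 2 and 3 it held 2.48%, 3.03% and 9.03%, and the rates there were 28.4, 56.1 and 30.2. The higher rate of replicate 2 includes reads of the 54 genes, so it restates the pattern in part. No biological explanation was tested.

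The replicate 3 pair differed in its response to LPS: the cytokine list responded less than in replicates 1 and 2 (median difference −1.29 on the log2 scale, 95% bootstrap interval over genes −2.27 to −0.47, lower for 13 of 15 genes). The interferon-stimulated list responded more (median difference 0.52, 0.42 to 0.65, higher for 34 of 37 genes), so a lowering of both lists was not seen. The p200 list, also of interferon-response genes, did not follow (median difference −0.215, lower for 5 of 8 genes). The contrast of the lists is the pattern itself, seen before the test was chosen, so it is no separate test of a weaker LPS stimulus. A single scaling factor moves every gene alike and would not alone part the list medians, which differed by 1.81 (0.90 to 2.83). That difference restates the pattern too. Genes are not independent replicates and only 1 pair differs, so a difference of that culture stays open, and no biological explanation was tested.

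The 6 libraries make only 10 splits of 3 against 3, too few for a share under 0.05. The real split called 4388 genes, 2125 of them at least 2-fold, and the highest of the other splits called 0 and 0, so 1 of 10 splits gave as many in each case. For the gene lists under camera with the preset correlation, 6 of the 10 splits called at least as many as the real 14, the highest of the others calling 15. Of the 4 splits that part all 3 number pairs, the 3 other than the real one called 13, 15 and 12 lists and 0 genes. Every split other than the real one mixes both treatments on each side. The LPS effect then widens the residual spread, and part of it remains between the sides. The other splits are thus no comparison free of the LPS effect, for genes or for lists.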
